A study of Drosophila melanogaster with 4 samples.

How the data were processed

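The series measured the binding of RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of wild-type Oregon-R Drosophila melanogaster larvae of instar 3. Per the labels' protocols, formaldehyde was the fixative, chromatin was sheared by sonication, and the incubation with antibody lasted 15 hours. The labels name the antibody as RNA Pol II from abcam and give 2 ChIP replicates and 2 input libraries (chromatin without immunoprecipitation). Their numbers are crossed: input replicate 1 served ChIP replicate 2, and input replicate 2 served ChIP replicate 1.

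Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The program that called the regions, its threshold and its filters are not given in the sources used here. The authors deposited 3 lists of regions with coordinates on FlyBase release 5 of the genome, per the file headers: 1 list for each ChIP replicate and 1 list for the replicate set. Each region was deposited by the authors as enriched or depleted, with 1 log2 value (the score). The base and make-up of this score are not stated, and were found from the values. All 7524, 6489 and 8320 scores of replicate 1, replicate 2 and the replicate set equalled log2 of a ratio of 2 whole numbers plus 1 constant per list (−0.08, 0.27 and 0.09), within a relative tolerance of 1e-11 and with denominators up to 20000. After small random noise was added to the scores, 0.545%, 0.848% and 0.529% still passed. The whole numbers are read here as ChIP reads over input reads in the region, and the constant as a scaling between those libraries; the files state neither. Since a ratio keeps its counts only in lowest terms, each recovered count is a lower limit. Summed over enriched regions, these limits came to 5.06 M ChIP and 1.97 M input reads in replicate 1, 4.70 M and 1.93 M in replicate 2, and 10.8 M and 4.86 M in the replicate set. The total depth of the libraries is unknown. The standard error of a score from counting alone, computed from the limits and so an upper bound, had a median of 0.13, 0.12 and 0.09 on the log2 scale. Where a fold is given, it is 2 to the power of the score, and its 95% interval is a normal interval on the log scale that covers counting error only.

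The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 and were equal. Main results used all enriched regions. Regions listed as depleted were kept apart. A region was called shared when it overlapped a region of the other list by at least 1 bp, and the share was compared with 1000 random non-overlapping placements of the other list's regions on the same sequences (one-sided permutation test). Coverage in both replicates means bases inside regions of both lists. The X was compared with the arms 2L, 2R, 3L and 3R by permuting bins of 1 Mb (100000 resamples, two-sided). Scores of regions matched 1 to 1 were correlated across regions, with 10000 shuffles for the p-value. Shares of regions carry 95% Wilson intervals. Scores were ranked and tested only within a list, because the constant differs between lists. Between the replicates they were correlated, and the spread of their difference was taken around its linear trend on the mean score. This removes a constant offset and also any linear change of the difference with the score. Folds of 1 region in different lists are set side by side without reading a difference in level from them. With 2 replicates, values are given per replicate or as mean ± SD (n = 2). Nothing in the labels says that the replicates came from separate larval collections, so the spread between them may be technical.

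On simulated lists of 7517 regions made for the comparison of the replicates, a true shared share of 50% gave 57.9% against 57.7% expected with chance overlaps, and 80% gave 80.8% against 80.7%. With the labels of the 122 real bins permuted, 6 of 100 runs gave p under 0.05, and with the X raised by 10 percentage points 100 of 100 runs did. The first rate follows from the test's construction, which permutes the same labels, and says nothing on dependence between neighbouring bins. No smaller shift was tried, so the power to detect a difference of a few points is unknown. In simulated regions with known read counts, some of them set to the same small ratio, 100% of the counts in lowest terms were recovered. The simulation does not test how the constant is found where no small ratio recurs.

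Regions named in the text were chosen by a rule: the 10 highest scores of the replicate set list among regions overlapping both replicates, and the 5 longest stretches covered in both. The samples' groups, tests, alternatives and this rule were fixed before the data were examined. Planned tests against genes (position relative to genes, occupied start sites, gene lists and gene bodies) were not made. They needed gene positions on release 5, while the gene table used here is on release 6 and coordinates were not converted. For the same reason regions are named by coordinates, and no gene, exon or UTR is assigned to them. Alternatives were a reciprocal overlap of 50%, the higher-scoring 50% of each list, regions of at least 200 bp, the 6 main arms alone, the replicate set list, and each replicate alone. Chosen after seeing the data were placement within 50 kb and leaving out the 2 Mb at the centromeric end of each large arm's sequence. So were a width filter on the replicate set, the 6 main arms for that list, and tests of single arms and of chromosome 4. The tests of the closing section and the recovery of counts from the scores were chosen then too. The input libraries entered only through the authors' ratios.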

Results

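Pol II occupancy was mapped in nuclei of wild-type Drosophila melanogaster larvae of instar 3, the last larval stage, in 2 ChIP replicates with 2 input libraries. Replicate 1 had 7517 enriched regions over 24.4 Mb and replicate 2 had 6487 over 21.5 Mb. The replicate set list had 8273 regions over 28.3 Mb. Regions had median widths of 2245, 2281 and 2223 bp in these 3 lists, with quartiles of 1938 and 3640 bp in replicate 1. Regions of 10 kb or more made up 2.77% of replicate 1 and 2.90% of replicate 2, and held 12.5% and 13.7% of the bases. The score, a log2 ratio read as ChIP over input, had a median of 0.78 in replicate 1 (1.72-fold), 1.04 in replicate 2 (2.05-fold) and 0.62 in the replicate set (1.54-fold). In replicate 1, 88.2% of the enriched regions had a 95% counting interval wholly above 0, as had 89.7% in replicate 2. Intervals and read limits cover counting error only, the intervals are at their widest because counts are known only in lowest terms, and reads without molecular identifiers are not independent molecules.

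Which loci carried the most Pol II was read from the 10 highest scores of the replicate set among regions found in both replicates. All 10 lay on the main arms, 5 of them on 3R, and were 2.64 to 16.2 kb wide. The highest was on 3L, 3191494 to 3200610, at 22.6-fold (95% counting interval 19.8 to 25.7), with 20.3-fold in replicate 1 and 26.8-fold in replicate 2. The next was on 3R, 17121280 to 17132146, at 21.0-fold (19.9 to 22.3), with 17.2-fold in replicate 1, the higher of 2 regions there, and 26.2-fold in replicate 2. A region on 3R from 8327168 to 8337980 reached 20.1-fold (18.7 to 21.5), and its neighbour from 8289876 to 8294618 reached 16.1-fold (13.3 to 19.6). Also on 3R, the 16.2 kb region from 7773690 to 7789858 stood at 13.7-fold (13.2 to 14.1); it spanned 2 regions in each replicate, the stronger at 14.7-fold in replicate 1 and 21.4-fold in replicate 2. The 3R region from 11067226 to 11073658 stood at 15.3-fold (10.7 to 21.7). On 2R, the region from 14423170 to 14428530 had 15.3-fold (14.5 to 16.3) and the 2.64 kb region from 8866920 to 8869560 had 13.7-fold (12.7 to 14.8). The X contributed 5792804 to 5800762 at 12.1-fold (10.8 to 13.6), and 2L contributed 12044042 to 12049192 at 11.6-fold (11 to 12.2). None of the 10 ranked below 19 among the 7517 scores of replicate 1 or below 12 among the 6487 of replicate 2, and all 10 overlapped a region of each replicate by at least 50% both ways. These ranks and overlaps follow in part from the choice of regions, since the replicate set list is not independent of the replicates. In 3 regions of the replicate set the score was above that of the tenth region named here, but neither replicate list had a region there.

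**Figure D1:**
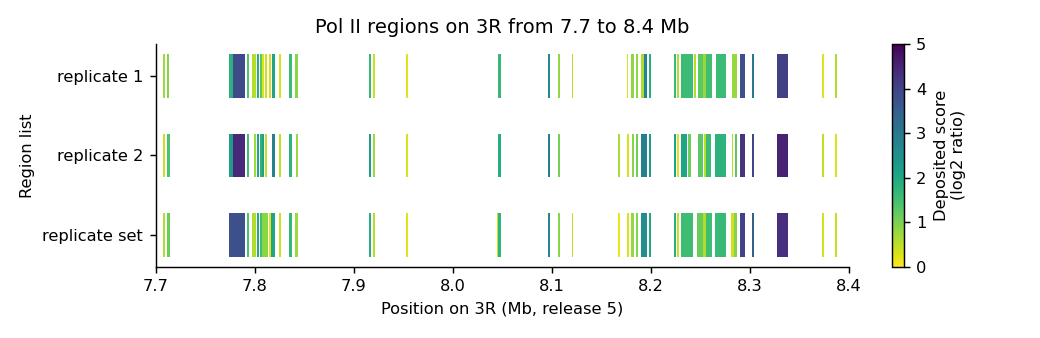
Regions of the 3 lists on 3R from 7.7 to 8.4 Mb (release 5); the x axis is position in Mb, each row is a list, each bar is a region and its colour is the deposited score (log2 ratio). The darkest bars, at 7773690 to 7789858, 8289876 to 8294618 and 8327168 to 8337980 in the replicate set, have counterparts in both replicates.

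The longest Pol II domains were read from bases inside regions of both replicates, which formed 6572 stretches with a median of 2197 bp; 117 were 10 kb or longer. The longest spanned 41.6 kb on 3L, 17946058 to 17987702, inside regions of 41.6 kb in replicate 1 and 51.4 kb in replicate 2. A stretch of 36.6 kb lay on the X, 1528599 to 1565243, and 1 of 36 kb on 2L, 13022876 to 13058883. On 3R a stretch of 30.5 kb ran from 19012105 to 19042578, and on 2R 1 of 27.3 kb ran from 6404562 to 6431831. These long domains were not the strongest ones. Their scores in the replicate set were 2.81-fold on 3L, 3.45-fold on the X, 2.30-fold on 2L, 2.53-fold on 3R and 3.73-fold on 2R, between the 73.3 and 90.4 percentiles of that list. Across all regions of a list, wider regions had higher scores (Spearman's rho 0.65 in replicate 1 and 0.62 in replicate 2, across regions, which are not independent replicates).

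Whether Pol II occupied the chromosomes alike was asked by the share of bases covered. The arms 2L, 2R, 3L and 3R together were 19.8% covered in replicate 1 and 17.5% in replicate 2, a mean of 18.6% ± 1.6 (SD, n = 2). The X was 18.4% ± 2.1 (SD, n = 2) covered. In bases common to both replicates, the X had 15.3% and the autosomal arms 15.9%, a difference of −0.61 percentage points. That difference was within the variation between 1 Mb bins (permutation test over 122 bins, two-sided, p = 0.64), and its sign differed between the replicates, at 0.05 points in replicate 1 and −0.57 in replicate 2. Among the 5 large arms, 2R was the most covered at 18.7% in both replicates, 3.61 points above the other 4 large arms (permutation over bins, p = 0.0049, adjusted p = 0.025 over 5 arms). The arm 2L, 14.1% covered, lay 2.03 points below the other large arms without passing the threshold (permutation, adjusted p = 0.28). For 3L, 3R and the X the permutation test gave adjusted p-values of 0.60, 0.75 and 0.75. Neighbouring bins are not independent, and these p-values take no account of that. Read depth may also differ between chromosomes. Median input reads per kb in X regions, in lowest terms, were 0.71 of the autosomal level in replicate 1 and 0.74 in replicate 2. Whether this changed how many bases were called was not tested.

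Chromosome 4, a small chromosome known for heterochromatin interspersed with active genes, had the most regions per Mb of the 6 main arms. It carried 79.2 ± 8.4 regions per Mb (SD, n = 2) against 57.3 ± 5.7 on the autosomal arms, and was 29.7% ± 3.6 (SD, n = 2) covered. In bases common to both replicates it was 23% covered, a share reached by 5.97% of 9122 overlapping stretches of its length along 2L, 2R, 3L and 3R. That percentage depended on the list used: for the coverage in replicate 1 alone it was 9.57%, in replicate 2 alone 0% and in the replicate set 1.11%. The order turned when only the higher-scoring 50% of each list was kept: chromosome 4 was then 7.13% covered and the autosomal arms 9.94%, and 78.9% of stretches were covered as much, so that it lay within the spread of these stretches. The median score on chromosome 4 was 0.57 in replicate 1 and 0.78 in replicate 2, below the 0.78 and 1.04 of the 6 main arms together. Median input reads per kb in its regions, in lowest terms, were 1.21 and 1.08 of the autosomal level in these replicates. Whether depth changed its coverage was not tested. The heterochromatic scaffolds (the Het sequences of chromosomes 2, 3, X and Y) were 2.59% ± 0.97 (SD, n = 2) covered and the unplaced sequence U 1.77% ± 0.20 (SD, n = 2). Sequence gaps lower these shares by an amount not measured here. The single YHet region, from the Y chromosome, was found in both replicates, and no region lay on Uextra.

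**Figure D2:**
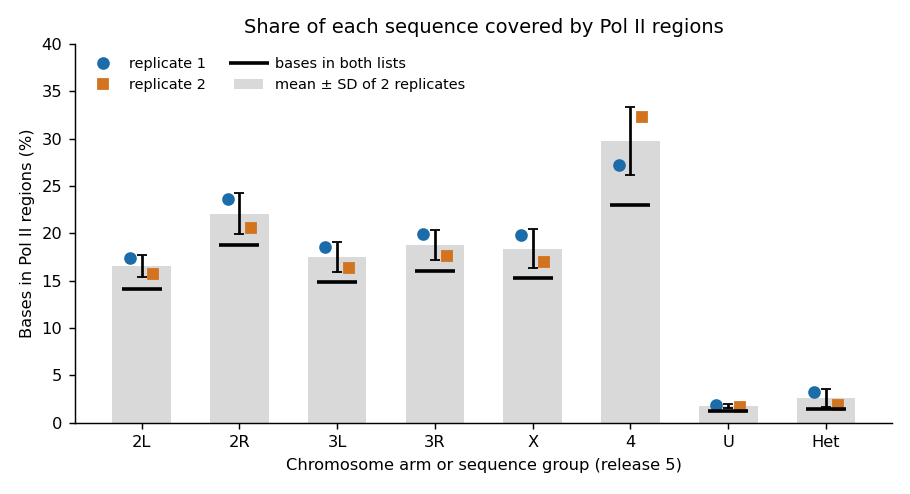
Share of bases inside Pol II regions (y axis, %) for each chromosome arm, the unplaced sequence U and the Het scaffolds (x axis); bars and error bars are the mean ± SD of 2 replicates, points are the replicates and black lines are bases common to both lists. Chromosome 4 stands highest at 29.7% and 2R is highest among the large arms.

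**Figure D3:**
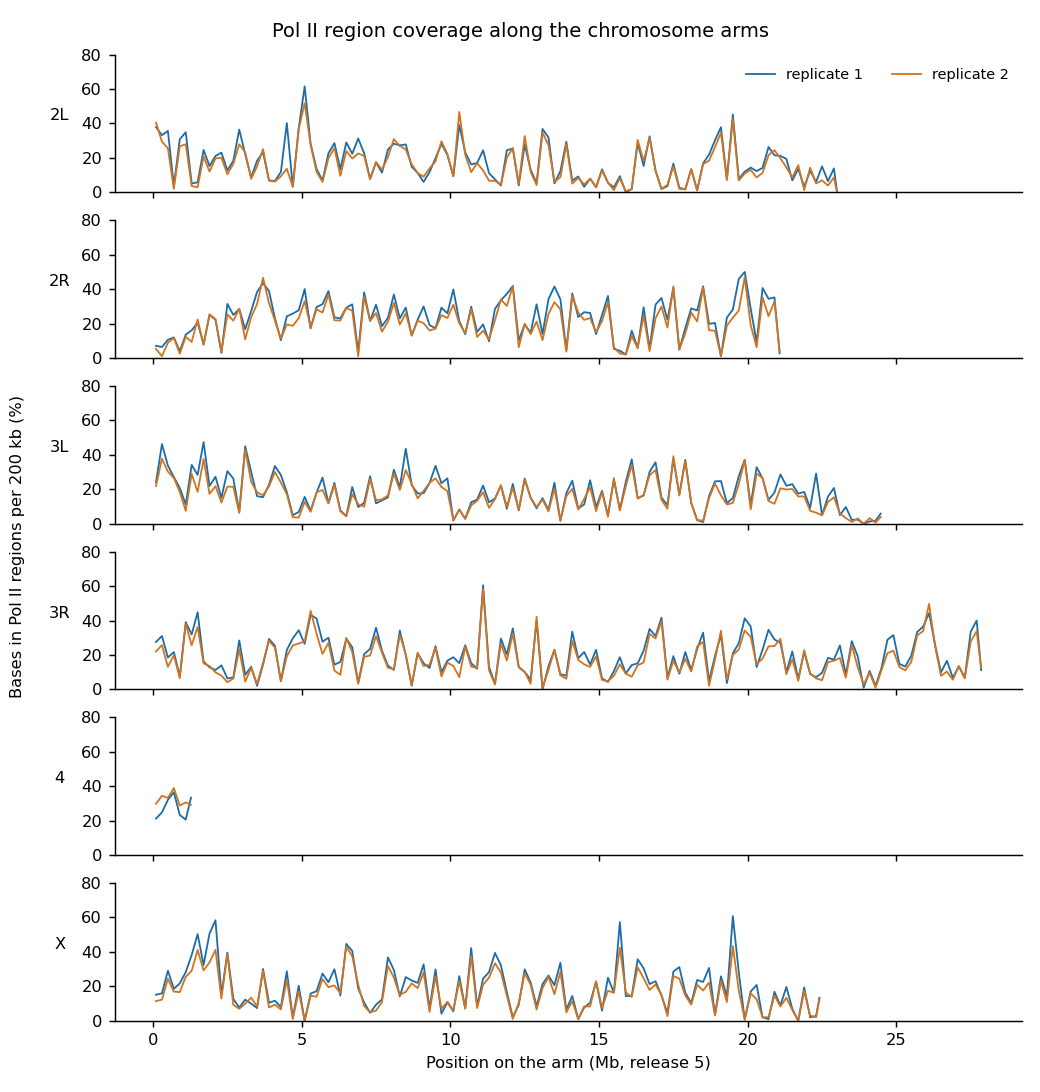
Share of bases inside Pol II regions (y axis, % per bin of 200 kb) along each main arm (x axis, position in Mb on release 5), with 1 line per replicate. Across bins Spearman's rho between the replicates was 0.95 to 0.98 on the 5 large arms and 0.39 over the 7 bins of chromosome 4, and single bins parted widely, such as 2L from 4400001 to 4600000 with 40.2% in replicate 1 and 13.7% in replicate 2.

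How far the replicates shared their regions shows 1 part of the error of the maps above. Errors common to both replicates, such as those of the antibody or the calling, do not show in their overlap. Of the replicate 1 regions, 80.8% (95% Wilson interval 79.9 to 81.7) overlapped a region of replicate 2, where random placement gave 31.9% ± 0.5 (SD over 1000 placements). Of the replicate 2 regions, 93.5% (92.9 to 94.1) overlapped replicate 1, where random placement gave 36.4% ± 0.6. In both cases the permutation p was 0.001, the smallest that 1000 placements can give (one-sided). Both lists covered 19.3 Mb in common, 72.8% of the 26.6 Mb covered by either. Shared regions were the stronger ones: 98.2% of replicate 1 regions in the top quartile by score were shared and 62.8% of those in the lowest quartile, and in replicate 2 these shares were 99.6% and 79.4%. The 1440 regions of replicate 1 alone had a median score of 0.54 and a median width of 1668 bp, against 0.94 and 2469 bp for shared regions. Sharing varied between sequences and replicates. For replicate 1 it was 44.1% (35.8 to 52.8) on the Het scaffolds, 59.3% (48.4 to 69.3) on U and 81.7% (80.8 to 82.6) on the 6 main arms, with 82.6% (74.7 to 88.5) on chromosome 4. For replicate 2 it was 86.9% (76.2 to 93.2) on the Het scaffolds, 78.2% (65.6 to 87.1) on U and 93.7% (93.1 to 94.3) on the 6 main arms, with 77.8% (68.6 to 84.8) on chromosome 4. Chance overlap differs between these sequences. Replicate 2 covered 1.91% of the Het scaffolds, 1.63% of U, 17.6% of the 6 main arms and 32.3% of chromosome 4. Random placement alone gave 32.7% for replicate 1 and 36.9% for replicate 2 on the 6 main arms. Without a chance value for each sequence, the shares above cannot be compared between them.

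Regions matched 1 to 1 numbered 4851, which is 64.5% of replicate 1 and 74.8% of replicate 2. All other regions were left out of the correlations. The matched regions had closely related scores, with Pearson's r = 0.95 and Spearman's rho = 0.93 across regions. The permutation p was 0.0001 for both, the smallest that 10000 shuffles can give. With 2 correlations computed, neither p changes after adjustment. The difference, replicate 2 minus replicate 1, rose with the mean score of the pair, with a slope of 0.18, and had an SD of 0.25 on the log2 scale. Around the trend line the difference between replicates had an SD of 0.22 on that scale, and its counting error had a median of at most 0.19. An SD and a median are unlike measures, so these values alone do not show spread beyond counting error. The deviation from the trend exceeded its 95% counting error in 10.3% of the matched regions.

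**Figure D4:**
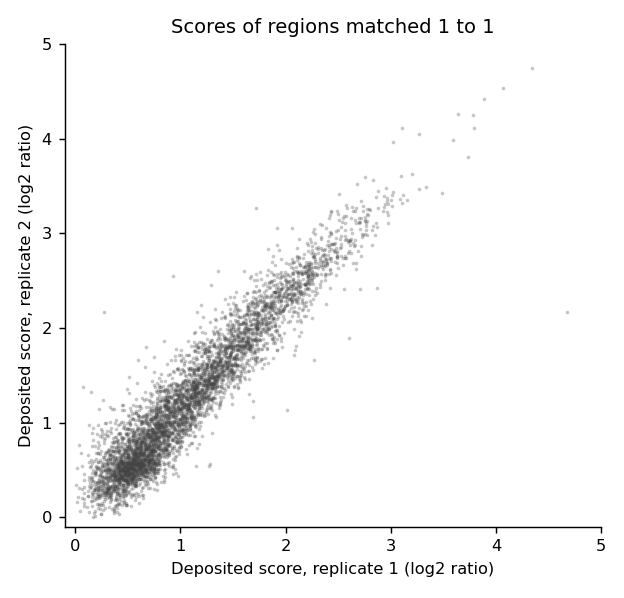
Deposited scores (log2 ratio) of regions matched 1 to 1 in replicate 1 (x axis) and replicate 2 (y axis), 1 point per region. The 4851 points lie along a line (Spearman's rho 0.93), with 1 point far to the right that belongs to the unplaced sequence U.

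The replicate set list was compared with the single replicates to see which regions it added. It held 97.2% of the replicate 1 regions and 99.1% of the replicate 2 regions. Of its 8273 regions, 66.4% (95% Wilson interval 65.3 to 67.4) overlapped both replicates, 14.8% replicate 1 alone and 4.59% replicate 2 alone. The remaining 1180 regions, 14.3% (13.5 to 15.0), overlapped neither, with a median score of 0.36 and a median width of 1213 bp, against 0.99 and 2929 bp for regions in both. The list is not independent of the replicates, so no test was made.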

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

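Besides the enriched regions, the lists hold regions named as depleted that entered no comparison above. There were 47 in the replicate set and 7 in replicate 1, both above the 3 regions taken as the limit for a count of 0, and 2 in replicate 2. Their scores were close to 0, from −0.25 to −0.0019 in the replicate set. All 7 depleted regions of replicate 1 overlapped an enriched region of replicate 2. Of the 47 depleted regions of the replicate set, 36 overlapped an enriched region of a single replicate, 3 of them in both, while 1 and 2 overlapped a depleted region of replicate 1 and replicate 2. In every list, each enriched region had a score above 0 and each depleted region a score below 0, so the name followed the sign of the score.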

How the results depend on the processing

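The overlap of the replicates stayed above random placement, and the score correlations above 0, under every alternative tried for them; placement within 50 kb, chosen after seeing the data, raised the random overlap to 37.5% and 41.8%. The share of replicate set regions found in both replicates and in neither was 58.1% and 17.7% with 50% reciprocal overlap, 72.0% and 12.1% in the higher-scoring 50% of each list, and 75.5% and 6.36% among regions at least as wide as the replicates' narrowest (1301 bp). On the 6 main arms, like that width filter chosen after seeing the data, 67.4% was found in both. Against 1 replicate at a time, 71.0% to 81.1% of the whole list was found. The X minus autosome difference reversed, without passing the threshold, to 0.000239 points in the higher-scoring 50%, 0.0487 in the replicate set list and 0.0475 without replicate 2, and was −0.569 without replicate 1; the cause was not tested. Coverage followed the list used. In the higher-scoring 50% it was 9.94% on the X, 9.94% on the autosomal arms, 7.13% on chromosome 4 and 0.369% on the Het scaffolds. In the replicate set list these were 22.8%, 22.8%, 36.6% and 4.06%. With 1 replicate left out the X had 16.9% to 19.8%, the autosomal arms 17.5% to 19.8%, chromosome 4 27.2% to 32.3% and the Het scaffolds 1.91% to 3.28%. Keeping fewer or more bases moves coverage by construction. Median scores on chromosome 4 were 0.57 in replicate 1 and 0.78 in replicate 2, against 0.78 and 1.04 on the 6 main arms. A cut by score therefore removes a larger share of its regions. Why its scores were lower was not tested. Tested values were judged by direction and threshold, others by the SD between replicates or the 95% interval, so a small shift counts where replicates nearly coincide. Of 68 alternative values, 34 stayed, 31 moved and 3 reversed; 7 of the 34 come from the filter at 200 bp, which removed 0 regions and so tests nothing. Alternatives for positions relative to genes, start sites, gene lists and gene bodies were not run, for want of gene positions on release 5. No paired analysis was possible because the input libraries have no region lists of their own here and the 2 ChIP replicates form a single group. Counting error was larger at low scores. In replicate 1 its median on the log2 scale was 0.15 in the lowest score quartile and 0.10 in the top one, both upper bounds since counts are lower limits. The effect of depth was not tested.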

Other observations

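The tests in this part were chosen after the data had been examined; those of width and of centromeres for the X scores were fixed before their own results were seen, the others after. Pol II regions were more clustered along the arms than uniform placement over each whole arm gives. Such placement also fills sequence gaps and stretches where reads cannot be placed. The comparison below therefore cannot separate these from clustering of Pol II itself. Of 1202 windows of 100 kb on the 6 main arms, 89 held no base covered in both replicates, against 2.0 ± 1.4 with random placement, and 13 were at least 50% covered, against 0.96 ± 0.89 (permutation p = 0.001 for both, one-sided, the smallest that 1000 placements can give). The densest window, on 3R from 26100001 to 26200000, was 75.4% covered. Next came 2R from 3600001 to 3700000 at 66.8%, 3R from 11100001 to 11200000 at 64.6% and the X from 1500001 to 1600000 at 63.9%. Coverage per window in the replicates had a Spearman's rho of 0.96 across all windows.

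Long stretches were free of regions in all 3 lists. Taking the longest stretch of each arm, that of the X ran for 341 kb from 21502219 to 21842941. That of 3L ran for 276 kb from 23745037 to 24020643 and that of 2R for 195 kb from 9511671 to 9707112. Sequence gaps inside such stretches were not measured. Stretches of at least 100 kb made up 16.6% of 2L, 15.2% of the X and 9.40% of 2R, while chromosome 4 had none, its longest being 51.6 kb. In the 2 Mb at the centromeric end of the arm sequence, coverage in both replicates was 3.62% on 3L against 15.9% on the rest of the arm. It was 6.41% against 16.1% on the X, 7.90% against 19.9% on 2R and 8.19% against 14.7% on 2L. The arm 3R went the other way, with 20.0% against 15.8%, in replicate 1 (25.1% against 19.5%) and in replicate 2 (21.6% against 17.3%). Heterochromatic sequence of these chromosomes is also held apart in the Het scaffolds, from 0.20 Mb in XHet to 3.29 Mb in 2RHet. How near each arm sequence comes to the centromere was not measured, so these contrasts may also reflect where it ends.

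The unplaced sequence U had the highest median score of any large group, 1.53 in replicate 1 and 1.55 in replicate 2, and held the top region of replicate 1, from 9501472 to 9503919. A candidate explanation is that ratios there rest on few input reads. Median input reads per kb (in lowest terms) in U regions were at most 10.8% of those on the main arms in either replicate. U regions of replicate 1 were shared less often with replicate 2 (59.3% against 81.7%, Fisher's exact test, two-sided, p = 3.6e-06). Replicate 2 covered 1.63% of U and 17.6% of the main arms, where random placement alone gave 32.7%. Chance overlap thus differs between them, and the test, which also treats regions as independent, cannot separate it from noisy ratios. The top region had a ratio of 27 to 1 in lowest terms, with a counting interval of at most 3.47- to 188-fold, and replicate 2 ranked it 794; its true number of input reads is unknown. What kind of sequence these reads came from stays open.

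Of the 1180 replicate set regions absent from both replicates, 60.8% were narrower than 1301 bp, the narrowest width in either replicate list. A lower minimum width could therefore account for part of them. The other 462 were at least that wide in the replicate set. Their width as called in a single replicate is unknown, so a width limit cannot be excluded for them either. Only 6.44% of the 1180 regions lay on U or the Het scaffolds, which argues against those sequences as the main source. Their median score stood at the 22.1 percentile of the list, but a low score does not set them apart: regions shared with replicate 1 alone stood at 25.5 and with replicate 2 alone at 10.3, so why they were listed only there stays open. Input reads per kb at the third quartile were 248 in the replicate set and 118 and 131 in the replicates, so the set had 99.1% of their sum, as pooled reads would give. The 3 unshared regions with scores above the tenth named region had ratios of 13 to 1 (U, 1269328), 11 to 1 (2L, 21453400) and 11 to 1 (2R, 5040946) in lowest terms, with counting intervals reaching down to 1.81-, 1.51- and 1.51-fold at most, and their true counts are unknown.

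Median scores were higher for regions of the X than for those of the autosomal arms, 0.86 against 0.77 in replicate 1 (permutation over bins, two-sided, p = 9e-05) and 1.09 against 1.03 in replicate 2, where the difference did not pass the threshold (p = 0.11). In the replicate set the medians were 0.67 and 0.61 (permutation over bins, two-sided, p = 0.074). Without the 2 Mb at the centromeric end of each large arm's sequence, at least 94.9% of the difference of medians stayed in each replicate (permutation over bins, p = 0.00024 in replicate 1 and 0.15 in replicate 2). Lower scores there therefore did not account for the whole difference. Matched for width in 4 classes, the difference of the mean bin medians (the mean over 1 Mb bins of their median scores) was above 0 in each replicate, with a permutation p of at most 0.00064. How much was left depends on the measure. Of the difference of mean bin medians, which that p tests, 61.4% was left in replicate 1 and 88.0% in replicate 2. Of the difference of medians, averaged over the 4 width classes, 31.2% and 28.1% was left. Widths can still differ within a class, so wider regions on the X cannot be excluded as the source of the difference. A stricter criterion tried after the result was seen, a median difference above 0 in each width class, was not met (−0.12 to 0.09 over both replicates). Median input reads per kb on the X were 0.71 of the autosomal level in replicate 1 and 0.74 in replicate 2 (0.744 in the higher case). ChIP reads were 0.78 and 0.79 of it, although at the third quartile of replicate 2 the ChIP ratio, 0.74, was no higher than the input ratio, 0.75. Input and ChIP reads are the parts of the score itself, and fewer X copies would lower both. These ratios therefore cannot tell whether X copy number contributes. The sex of the larvae is not given in the labels, so a pool of both sexes and any sex-linked biology were not tested.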
